A study of Mus musculus with 8 samples.

How the data were processed

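RNA from sorted microglia and brain T cells of aged C57BL/6 mice given IL-5 or PBS was sequenced as single-end reads in 8 libraries, 2 per group. The submitters' processing notes name bcl2fastq 2.20.0.422, FastQC 1.0.0, STAR 2.5.3a, Cufflinks 2.0 and DESeq2 1.1 with the mouse builds mm10 and GRCm38, and name no counting tool and no strand setting. The authors deposited a table of raw read counts per gene, whole numbers with no scaling, with 24953 entries and 1 column per library.

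The table held 2 summary entries, reads outside annotated genes and reads that could belong to several genes, which were kept apart as measures of quality. Reads outside genes made up 15.2% to 25.5% of each column and ambiguous reads 1.39% to 1.77%. A further 27 genes were left out because 53 of their cells were not numbers: 26 genes whose names had been turned into dates, with cells in the microglia IL-5 columns that could not be read, and 1 gene with 1 such cell in T cells IL-5 replicate 1. The readable PBS cells of the date-named genes held 0.0691% of the PBS counts. This left 24924 genes, of which 24390 symbols (97.9%) matched exactly 1 gene of GENCODE M21 on GRCm38, the source of all coordinates. Of 861 genes on the lists described next, 23 were not in the table analysed, among them the mitochondrially encoded genes and constant regions of antigen receptors.

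Gene counts per library ranged from 23536908 to 30423828. Levels are counts per 1000000 gene counts (CPM). A count of 0 allows up to 3 counts, or 0.0986 to 0.128 CPM depending on the library, and folds against a group at 0 were computed against 3 counts per library. These floors cover counting error only, since reads without molecular identifiers are not independent molecules.

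Genes were tested with the edgeR 4.0.16 quasi-likelihood test (R 4.3.3) on TMM-scaled counts with robust dispersion, after filterByExpr with a minimum count of 10. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Microglia and T cells were fitted separately for IL-5 against PBS, and all 8 libraries together for the difference of the responses and for T cells against microglia in PBS mice. The standard error of a log2 fold change was taken from the fold change and its F statistic. Gene lists, 46 in all with 28 of cell states and 18 of cell identities, were written from general knowledge and tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01. Camera was repeated with an estimated correlation. The test fry, which takes the members of a list without setting them against other genes, was run beside it. Lists with fewer than 5 tested members got no test. List medians are over the fitted log2 fold changes of their tested members.

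The groups, tests, alternatives, gene lists and the rule for named genes were chosen before the data were examined. The rule took, in each IL-5 comparison, the genes past the threshold with the largest change at a mean of at least 5 CPM and no overlap between groups, or the 5 with the smallest p in each direction where too few passed. It added up to 4 members with the smallest p from each state list that passed, up to 3 of the most abundant members of each identity list, and a fixed set that includes Il5ra, Csf2rb, Cish, Tnf and the main markers. For the difference of responses it took the 5 genes with the smallest p in each direction, and for T cells against microglia the members of both marker lists.

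The pipeline was tested on simulated data in which 2-fold, 4-fold and 16-fold changes were placed in 200 genes. With the spread of these libraries edgeR recovered 0%, 3.0% and 39.4% of them in microglia, with 4 unchanged genes called, and 0%, 14.9% and 54.5% in T cells, with 11 unchanged genes called. DESeq2 1.42.0 recovered 81.8% and 75.8% of the 16-fold changes, with 156 and 152 unchanged genes called. A shifted list was called in each of 3 simulated comparisons, and 0 of 20 unshifted lists in each. The genes of that list simulation were independent and had a much lower spread than these libraries. It therefore does not show how often lists of correlated genes are called by error.

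The alternatives were DESeq2, RLE size factors, scaling by library size only, no filter, a filter at 5 CPM in at least 2 libraries, the replicate number as a block, all 8 libraries in one fit, and leaving out each library in turn. Chosen after the data were seen were offsets adjusted for GC content or transcript length, scaling of the libraries to the marker list of the cell type, and the list tests under other filters and with each library left out. Groups of 2 allow 6 assignments of the labels, so an exact permutation test could not reach the threshold and was not used for the comparisons. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.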

Results

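RNA was sequenced from microglia and from brain T cells that had been sorted by surface markers from C57BL/6 mice aged 20 to 22 months. The mice received either interleukin-5 (IL-5), a cytokine that acts on eosinophils and B cells, at 2 µg each day over 2 days, or phosphate-buffered saline (PBS). The 8 libraries formed 4 groups of 2: microglia after PBS, microglia after IL-5, T cells after PBS and T cells after IL-5. The libraries held 23536908 to 30423828 counts assigned to genes, so that 1 count stood for 0.0329 to 0.0425 counts per 1000000 (CPM). The labels do not say whether each library came from a separate mouse, so p-values of edgeR, DESeq2 and fry measure the spread between these samples. Camera at the preset correlation sets the genes of a list against all other genes and treats them as nearly independent. The permutation and binomial tests further below run over genes, not libraries. By fry no list passed in either IL-5 comparison (smallest fry adjusted p = 0.159 in microglia and 0.259 in T cells). Each fold change below is IL-5 over PBS unless another pair is named, with n = 2 libraries per group, and its error is the standard error (SE) of the model.

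Sorted cell type was the main division between the libraries. The first principal component of log2 CPM held 41.3% of the variance and placed the 4 microglia libraries between -192 and -129 and the 4 T cell libraries between 124 and 165. On the second component, with 14.8% of the variance, microglia IL-5 replicate 1 lay at -197, and the other 7 libraries lay between -80.9 and 93.8. That library also had the fewest genes with at least 1 count, 13172 against at least 14318 in the other microglia libraries, and its 10 most abundant genes took 25.9% of its gene counts against 19.8% to 20.9% in the others. On the third component, with 12.4% of the variance, T cells IL-5 replicate 1 lay at 180, and the other 7 libraries lay between -114 and 31.96.

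**Figure D1:**
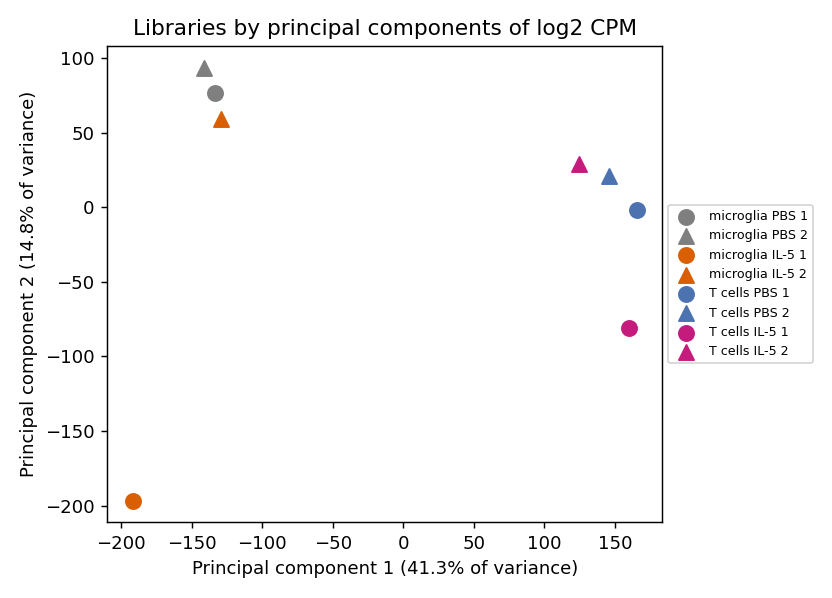
The 8 libraries by the first (horizontal) and second (vertical) principal component of log2 CPM, in arbitrary units, with the share of variance on each axis. Colours mark the 4 groups and shapes the replicate numbers; the cell types separate along the horizontal axis, and microglia IL-5 replicate 1 lies at -197 on the vertical axis.

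The comparison of T cells with microglia in PBS mice asked what the sorted populations contained. All 16 markers of microglia tested were lower in T cells over all genes tested, with a median log2 fold change of -12.54, and all 16 when adjusted over the list alone. P2ry12, the purinergic receptor that microglia use to sense nucleotides, measured 3170 and 2373 CPM in microglia and 0.23 and 2.21 CPM in T cells (log2 fold change -11.84, SE 1.33, edgeR adjusted p = 0.00168). Tmem119, a microglial surface protein, was lower by -13.05 (SE 1.05, edgeR adjusted p = 0.000544). Of 14 T cell markers, 7 were higher over all genes tested and 13 when adjusted over the list alone, with a median of 6.02. They included Cd3d, a chain of the T cell receptor complex (5.003, SE 0.64, edgeR adjusted p = 0.00235), and Thy1, a T cell surface glycoprotein (4.80, SE 0.47, edgeR adjusted p = 0.000712).

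The T cell libraries carried mainly markers of CD8 cells: Cd8b1, a chain of the CD8 coreceptor, measured 1174 and 1263 CPM after PBS, and Cd4, the coreceptor of helper cells, 31.1 and 72.9 CPM. Transcripts of other cell types were present in both populations. Ttr, which encodes transthyretin and is made in the choroid plexus, was the most abundant gene of all 4 T cell libraries, at 45089 and 65068 CPM after PBS, and measured 33495 and 39917 CPM in PBS microglia. S100a8, a calcium-binding protein of neutrophils, ranged from 5496 to 10490 CPM over the microglia libraries. In all, 396 genes were higher and 709 lower in T cells among 15397 tested (edgeR quasi-likelihood test, adjusted p under 0.05). The balance turned with library-size scaling, to 919 higher and 376 lower, and the counts were 641 and 1081 without a filter and 1226 and 1623 in DESeq2. With an estimated correlation between genes the list calls were lost, with adjusted p = 0.0798 with an estimated correlation for the microglia markers and adjusted p = 0.221 with an estimated correlation for the T cell markers. Both lists passed by fry (fry adjusted p = 0.000636 and 0.0135). The counts moved with single libraries, to 159 higher and 349 lower without microglia PBS replicate 1, 134 and 377 without microglia PBS replicate 2, 170 and 357 without T cells PBS replicate 1, 150 and 430 without T cells PBS replicate 2, 803 and 1146 without microglia IL-5 replicate 1, and 831 and 1197 without microglia IL-5 replicate 2.

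The comparison of microglia after IL-5 with microglia after PBS asked how the cytokine changed the program of these cells in aged mice. Genes of mitochondrial respiration and of the ribosome rose as groups at the preset correlation, but neither list passed by fry (fry adjusted p = 0.619 each). The nuclear-encoded oxidative phosphorylation genes rose with a median log2 fold change of 0.97 (47 of 58 above 0, camera adjusted p = 9.16e-11), which was lost when the correlation between genes was estimated (adjusted p = 0.715 with an estimated correlation). Cytosolic ribosomal protein genes rose with a median of 0.44 (56 of 78 above 0, camera adjusted p = 5.17e-06; adjusted p = 0.715 with an estimated correlation). No member of either list passed the test over all genes, or adjusted over the list alone, where the count was 0 in edgeR for both. Ndufb11 and Ndufs6, which encode subunits of respiratory complex I, had log2 fold changes of 1.46 (SE 0.57) and 1.66 (SE 0.64), and Uqcrc1, a core subunit of complex III, one of -1.28 (SE 0.40). Rps28 and Rpl23, proteins of the small and the large ribosomal subunit, had log2 fold changes of 1.55 (SE 0.61) and 1.43 (SE 0.56). Without microglia IL-5 replicate 1 the medians were 0.37 and 0.22, and without microglia IL-5 replicate 2 they were 1.55 and 0.68, with both lists past the threshold each time. With the libraries adjusted for transcript length, a setting chosen after seeing the data, the ribosomal median was 0.042 and did not pass (camera adjusted p = 0.319). The oxidative phosphorylation median was then 0.44 and passed (2.96e-05). With library-size scaling the ribosomal median was 0.28 and the oxidative phosphorylation median 0.81.

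Lysosomal genes fell after IL-5, with a median log2 fold change of -0.79 (32 of 36 below 0, camera adjusted p = 3.04e-05; adjusted p = 0.82 with an estimated correlation). Genes of the disease-associated state of microglia fell with a median of -0.63 (21 of 29 below 0, camera adjusted p = 0.0491; adjusted p = 0.715 with an estimated correlation). Members of these lists called by edgeR numbered 0 over all genes and 0 adjusted over the list alone, and those at an unadjusted p under 0.05 numbered 3 and 2. Axl, a receptor tyrosine kinase that takes part in clearing dying cells (GRCm38 chromosome 7, 25757273 to 25788705), measured 87.1 and 83.4 CPM after PBS and 11.8 and 21.9 CPM after IL-5 (log2 fold change -2.23, SE 0.48; adjusted p = 0.964 in edgeR and 0.023 in DESeq2). Cst7, an inhibitor of lysosomal cysteine proteases, had a log2 fold change of -1.18 (SE 0.40), Ctsd, a lysosomal aspartyl protease, one of -1.09 (SE 0.60), and Ctsf, a lysosomal cysteine protease, one of -1.22 (SE 0.45). Without microglia IL-5 replicate 1 the lysosomal median was -0.30 and the disease-associated median -0.25, both past the threshold, and without microglia IL-5 replicate 2 the lysosomal median was -1.26. The lysosomal call was lost without microglia PBS replicate 1 (camera adjusted p = 0.191, median -0.82). The disease-associated call was lost without microglia PBS replicate 1 (0.502, median -0.79), PBS replicate 2 (0.201, median -0.54) or IL-5 replicate 2 (0.0551, median -0.58). The disease-associated call was also lost with relative log expression (RLE) size factors (0.0583) and when the libraries were scaled to the microglia markers (0.0939).

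Genes that mark resting microglia did not pass the test as a group. The homeostatic list had a median of -0.34 (21 of 30 below 0, camera adjusted p = 0.0786), and the microglia markers one of -0.24 (camera adjusted p = 0.486). Both lists passed without microglia IL-5 replicate 1, and the homeostatic list also with library-size scaling. Tmem119 had a log2 fold change of -0.93 (SE 0.46) and P2ry12 one of -0.26 (SE 0.43), both short of the threshold. Apoe, a lipid carrier raised in disease-associated microglia, had one of -0.74 (SE 0.50), and the inflammatory cytokines Tnf and Il1b had -0.73 (SE 0.48) and -0.51 (SE 0.38). Of the genes that act downstream of IL-5, Csf2rb, the shared beta chain of its receptor, had 0.70 (SE 0.86), and the STAT5 targets Cish and Socs2 had -0.80 (SE 1.01) and -0.40 (SE 0.94). Il5ra, the IL-5 binding chain of the receptor (GRCm38 chromosome 6, 106710357 to 106749037), had 0 counts in all 8 libraries, which allows up to 0.128 CPM in the shallowest of them. Without microglia IL-5 replicate 1 the Csf2rb value was -0.99, and without microglia PBS replicate 2 the Socs2 value was 0.40.

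No single gene passed the edgeR test in microglia: 0 of 13764 genes were higher and 0 lower, with 246 higher and 371 lower at an unadjusted p under 0.05 (688 by chance), while DESeq2 called 18 higher and 49 lower. The genes with the smallest p, none of which passed in edgeR (adjusted p = 0.964 each), included Plxdc1, a plexin-domain membrane protein, at 105 and 129 CPM after PBS and 17.7 and 18.4 CPM after IL-5 (log2 fold change -2.54, SE 0.44), and Mars, the methionyl-tRNA synthetase (-3.41, SE 0.64). Ccar2, a nuclear regulator of the deacetylase Sirt1 (-8.12, SE 1.32), and Itga7, a laminin-binding integrin (-7.44, SE 1.21), were close to 0 after IL-5, and Elp3, the catalytic subunit of Elongator, was at 0 there and at least 144-fold lower against a floor of 3 counts per library. On the higher side stood Itpr1, an intracellular calcium channel (2.78, SE 0.72), Hbb-y, an embryonic globin (3.78, SE 1.00), Smim22 (2.39, SE 0.66), the noncoding Gt(ROSA)26Sor (2.06, SE 0.52) and Lrrc38, a potassium channel subunit that was at 0 after PBS and at least 99-fold higher after IL-5. On TMM-scaled log2 CPM both IL-5 libraries lay above both PBS libraries for 17.4% of genes and below them for 21.1%, where chance gives 16.7% each. Without microglia IL-5 replicate 2 the counts were 532 higher and 723 lower.

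Transcripts of other cell types were also measured in the microglia libraries, and none of those named here passed with all libraries. Ttr measured 55913 and 59213 CPM after IL-5 against 39917 and 33495 CPM after PBS (log2 fold change 0.81, SE 0.49, edgeR adjusted p = 0.974), and without microglia IL-5 replicate 2 its value was 0.95 and past the threshold in edgeR. The choroid plexus and ependyma list had a median of 0.25 and a mean of -0.11 and did not pass (camera adjusted p = 0.509). Ccl5 and Nkg7, expressed by cytotoxic lymphocytes, had log2 fold changes of 1.11 (SE 0.39) and 1.19 (SE 0.41), and Cd79a, a chain of the B cell receptor, one of 1.33 (SE 0.42), none past the threshold. The share of reads outside annotated genes was 25.5% in microglia IL-5 replicate 1 and 15.2% to 16.99% in the other microglia libraries.

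**Figure D2:**
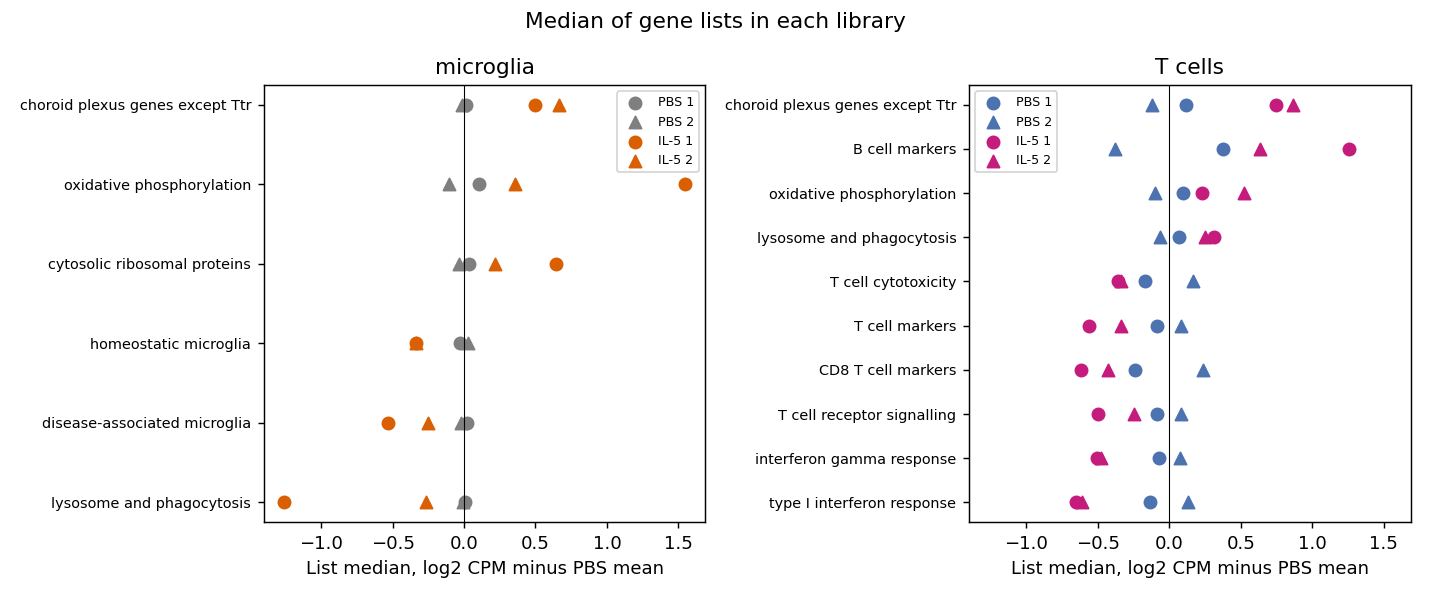
Median of each gene list in each library, as log2 CPM minus the mean of the PBS libraries of that cell type (horizontal axis), for genes of at least 20 CPM on average. Circles are replicate 1 and triangles replicate 2; in microglia the oxidative phosphorylation genes lie at 1.55 in IL-5 replicate 1 and 0.36 in IL-5 replicate 2, and in T cells the type I interferon genes lie at -0.65 and -0.61.

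The comparison of brain T cells after IL-5 with those after PBS asked for the effect of the cytokine on lymphocytes of the aged brain. Genes induced by interferons of type I and gamma fell together at the preset correlation, but neither list passed by fry (fry adjusted p = 0.715 and 0.259). The type I interferon list fell with a median log2 fold change of -0.61 (30 of 35 below 0, camera adjusted p = 3.84e-07; adjusted p = 0.696 with an estimated correlation). The interferon gamma list fell with a median of -0.50 (18 of 21 below 0, camera adjusted p = 1.32e-05; adjusted p = 0.696 with an estimated correlation). Members called by edgeR were 0 over all genes and 0 adjusted over the list alone, with 7 and 6 members at an unadjusted p under 0.05. Isg15, a ubiquitin-like antiviral protein, measured 108 and 121 CPM after PBS and 38.3 and 57.9 CPM after IL-5 (-1.20, SE 0.38). Ifit3, an RNA-binding antiviral protein, had -1.21 (SE 0.37). Psmb8, an immunoproteasome subunit, had -0.65 (SE 0.20) and also stands in the MHC class I list, which fell with a median of -0.24 (12 of 17 below 0, camera adjusted p = 0.045; adjusted p = 0.892 with an estimated correlation). The TNF and NF-kB list fell with a median of -0.34 (21 of 32 below 0, camera adjusted p = 0.0395, or 0.696 with an estimated correlation). Without a low count filter this median was -0.51.

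The interferon lists passed without each T cell library in turn. The MHC class I call was lost whichever library was left out, with camera adjusted p = 0.0962 without PBS replicate 1, where the median was -0.36, 0.242 without PBS replicate 2 (-0.19), 0.253 without IL-5 replicate 1 (-0.23) and 0.141 without IL-5 replicate 2 (-0.31). The TNF and NF-kB call was lost at a filter of 5 CPM (camera adjusted p = 0.0531), and without PBS replicate 2 (0.133, median -0.46), IL-5 replicate 1 (0.0947, -0.23) or IL-5 replicate 2 (0.251, -0.38). When the libraries were scaled to the T cell markers, a setting chosen after seeing the data, the MHC class I median turned to 0.092 and the TNF and NF-kB median was -0.006, and neither passed. The type I interferon and interferon gamma medians were then -0.28 and -0.16, and both passed.

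Genes of T cell identity and signalling fell in the same libraries. The T cell markers fell with a median log2 fold change of -0.42 (11 of 14 below 0, camera adjusted p = 4.42e-05; adjusted p = 0.801 with an estimated correlation). The CD8 markers fell with -0.50 (5 of 6 below 0, camera adjusted p = 0.0017; adjusted p = 0.808 with an estimated correlation). T cell receptor signalling genes fell with -0.47 (21 of 28 below 0, camera adjusted p = 3.06e-05; adjusted p = 0.696 with an estimated correlation). No member passed over all genes in edgeR, and adjusted over the list alone 2 of the CD8 markers passed and 0 of the other lists. Cd8b1, a chain of the CD8 coreceptor (GRCm38 chromosome 6, 71322788 to 71337494), measured 1174 and 1263 CPM after PBS and 737 and 835 CPM after IL-5 (-0.58, SE 0.15), and Cd8a had -0.56 (SE 0.16). Cd3g, a chain of the T cell receptor complex, had -0.65 (SE 0.19), Lck, the kinase that starts receptor signalling, -0.67 (SE 0.24), and Ptpn22, a phosphatase that restrains it, -0.86 (SE 0.20). Cd4 had 0.36 (SE 0.53), and its value was -0.12 without PBS replicate 1. The T cell marker call was lost without PBS replicate 2 (camera adjusted p = 0.0778, median -0.38). The CD8 call was lost without PBS replicate 2 (0.239, median -0.29), IL-5 replicate 1 (0.0947, -0.44) or IL-5 replicate 2 (0.0746, -0.62). The receptor signalling list passed without each library, with a median of -0.25 without IL-5 replicate 1. When the libraries were scaled to the T cell markers themselves, the receptor signalling median was -0.14 (camera adjusted p = 0.0771), the CD8 median -0.17 (0.213) and the marker median -0.091 (0.199). This scaling removes the mean change of the markers by construction, so the marker value is no test. The signalling list shares Cd3d, Cd3e, Cd3g, Cd247, Lck, Lat and Cd5 with the markers, and the CD8 list Cd8a and Cd8b1. The falls of these lists are therefore not separate results.

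Genes of effector and resident T cell states fell as well. The exhaustion and checkpoint list fell with a median of -0.52 (15 of 19 below 0, camera adjusted p = 0.00394; adjusted p = 0.696 with an estimated correlation). The tissue-resident list fell with -0.33 (12 of 16 below 0, camera adjusted p = 0.00756; adjusted p = 0.696 with an estimated correlation). The cytotoxicity list fell with -0.28 (18 of 28 below 0, camera adjusted p = 0.0056; adjusted p = 0.807 with an estimated correlation). Members called by edgeR were 0 over all genes and 0 adjusted over the list alone, with 3, 3 and 5 members at an unadjusted p under 0.05. Cxcr6, a chemokine receptor of resident T cells, measured 958 and 1189 CPM after PBS and 602 and 701 CPM after IL-5 (-0.67, SE 0.18). Tox, a transcription factor of exhausted cells, had -1.26 (SE 0.38), and Runx3, a transcription factor of CD8 and resident cells, had -1.03 (SE 0.31). Klrk1, the activating receptor NKG2D, had -1.27 (SE 0.33), and the death ligand gene Fasl had -1.02 (SE 0.34). The granule proteases Gzmb and Gzmk had -0.89 (SE 0.38) and -0.69 (SE 0.28), and the cytokines Ifng and Tnf had -0.09 (SE 0.26) and -0.997 (SE 0.54). The Ifng value was 0.088 without PBS replicate 2 and 0.026 without IL-5 replicate 2.

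The calls of these state lists changed when single libraries were left out. Without PBS replicate 2 the camera adjusted p was 0.0954 for exhaustion genes (median -0.54), 0.305 for resident genes (-0.36) and 0.531 for cytotoxicity genes (-0.062). Without IL-5 replicate 1 it was 0.0535 for resident genes, with a median of -0.084, and 0.0963 for cytotoxicity genes, with a median of -0.19. Without IL-5 replicate 2 it was 0.0914, 0.154 and 0.112 for exhaustion, resident and cytotoxicity genes, with medians of -0.37, -0.29 and -0.39. Without PBS replicate 1 the 3 lists passed, with medians of -0.80, -0.53 and -0.63. Scaled to the T cell markers, the cytotoxicity median turned to 0.051 and did not pass (camera adjusted p = 0.197), and the resident median lay at 0 (0.204). The exhaustion median was then -0.19 and passed (0.0377).

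Oxidative phosphorylation genes rose in T cells, with a median log2 fold change of 0.38 (57 of 58 above 0, camera adjusted p = 9.04e-14; adjusted p = 0.801 with an estimated correlation). Cox6a1 and Cox7b, subunits of cytochrome c oxidase, had 0.64 (SE 0.16) and 0.71 (SE 0.18). Lysosomal genes rose with a median of 0.25, or 0.28 with 1 member at 0 in a group set to 3 counts per library (27 of 36 above 0, camera adjusted p = 0.0157; adjusted p = 0.696 with an estimated correlation), including Cd63, a tetraspanin of late endosomes (0.88, SE 0.21), and Lamp2, a lysosomal membrane protein (0.68, SE 0.17). Ribosomal protein genes fell with a median of -0.12 (58 of 78 below 0, camera adjusted p = 0.00895; adjusted p = 0.92 with an estimated correlation), and their median was 0.21 when the libraries were scaled to the T cell markers. That scaling placed the oxidative phosphorylation median at 0.71 and the lysosomal median at 0.58, and the length adjustment placed the ribosomal median at -0.21. In each of these lists edgeR called 0 members over all genes and 0 adjusted over the list alone, with 15, 4 and 1 at an unadjusted p under 0.05. The oxidative phosphorylation list passed without each library, with a median of 0.23 without IL-5 replicate 2. The lysosomal call was lost without PBS replicate 2 (camera adjusted p = 0.531, median 0.19), IL-5 replicate 1 (0.382, 0.24) or IL-5 replicate 2 (0.154, 0.31), and the ribosomal call without IL-5 replicate 1 (0.214, median -0.031), while the ribosomal median was -0.22 without IL-5 replicate 2.

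Markers of the choroid plexus and of B cells rose in the IL-5 T cell libraries. The choroid plexus and ependyma list rose with a median of 0.79 (7 of 10 above 0, camera adjusted p = 0.00394; adjusted p = 0.804 with an estimated correlation), with 0 members called over all genes in edgeR and 4 adjusted over the list alone. Ttr (GRCm38 chromosome 18, 20665280 to 20674321) measured 65068 and 45089 CPM after PBS and 89983 and 91511 CPM after IL-5 (0.77, SE 0.18), and took 4.51% to 6.51% of gene counts after PBS and 8.998% and 9.15% after IL-5. Kcnj13, a potassium channel of choroid plexus epithelium, had 0.77 (SE 0.20), and Kl, which encodes klotho, 0.88 (SE 0.22). The B cell list rose with a median of 1.104 (9 of 10 above 0, camera adjusted p = 0.00394; adjusted p = 0.696 with an estimated correlation). In edgeR 0 of its members were called over all genes and 1 adjusted over the list alone, and its median was 1.08 with 1 member that was at 0 in a group set to 3 counts per library. Fcmr, the receptor for IgM on B cells, was at 0 after PBS and at 44.7 and 20.7 CPM after IL-5. It was at least 284-fold higher against that floor, which covers counting error only. Jchain, the joining chain of secreted antibodies, measured 0 and 7.23 CPM after PBS and 188 and 136 CPM after IL-5 (5.54, SE 1.80). Prg2, the eosinophil granule major basic protein, measured 0 and 0.12 CPM after PBS and 34.2 and 24.7 CPM after IL-5 (8.93, SE 1.92, GRCm38 chromosome 2, 84980461 to 84983632). The choroid call was lost without PBS replicate 2 (camera adjusted p = 0.0778, median 0.56) and without IL-5 replicate 2 (0.799, median 0.45), and its median was 0.49 without PBS replicate 1. The B cell call was lost without PBS replicate 2 (0.18, median 0.59) and without IL-5 replicate 1 (0.221, median 0.78).

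No single gene passed the edgeR test in T cells: 0 of 13897 genes were higher and 0 lower, with 355 higher and 245 lower at an unadjusted p under 0.05 (695 by chance), while DESeq2 called 403 higher and 255 lower. The genes with the smallest p, none of which passed in edgeR, included Cyfip2, a component of the WAVE complex that shapes the actin cytoskeleton (GRCm38 chromosome 11, 46193850 to 46312859). It measured 282 and 308 CPM after PBS and 117 and 121 CPM after IL-5 (-1.26, SE 0.22). Btla, an inhibitory receptor of lymphocytes, had -5.04 (SE 1.12), Efr3a, a membrane scaffold of lipid kinase signalling, -0.88 (SE 0.21), and Slc2a6, a member of the glucose transporter family, was at 0 after IL-5 and at least 181-fold lower. On the higher side, Arvcf, of the catenin family, had 7.82 (SE 1.31), Dcaf12l1 4.92 (SE 0.91) and Acap3, which acts on Arf GTPases, 4.86 (SE 0.97), and Rassf7 was at 0 after PBS and at least 261-fold higher after IL-5. Foxp3, the transcription factor of regulatory T cells, had -2.67 (SE 2.52), Cish had -0.45 (SE 0.32), and Csf2rb measured at most 1.61 CPM in any T cell library. On TMM-scaled log2 CPM both IL-5 libraries lay above both PBS libraries for 18.1% of genes and below them for 17.3%, where chance gives 16.7% each. Without PBS replicate 2 edgeR called 1 gene, a higher one.

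**Figure D3:**
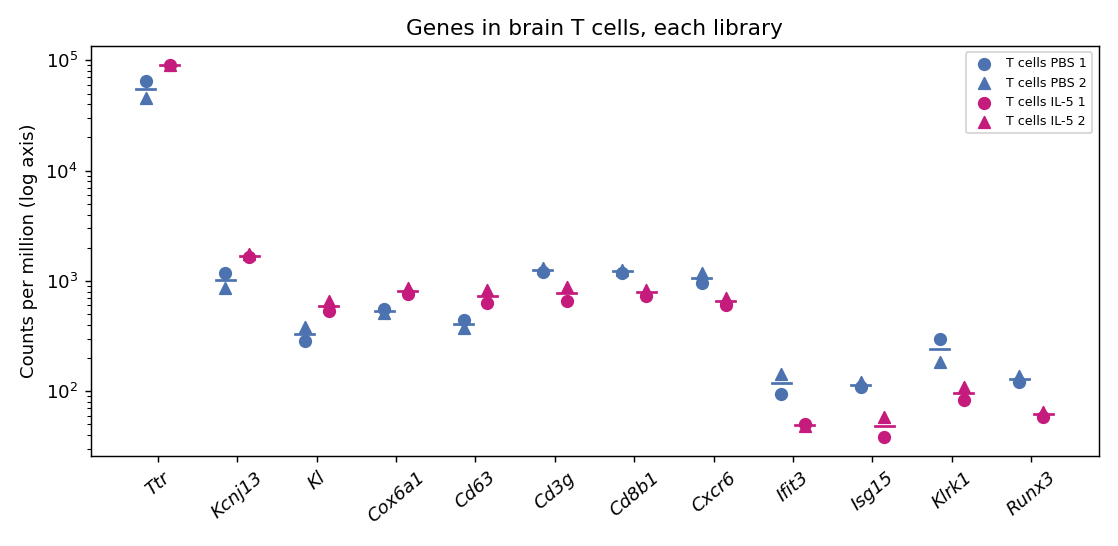
Level of 12 genes in each of the 4 T cell libraries, in CPM on a log axis, with the group mean as a line; circles are replicate 1 and triangles replicate 2. Ttr lies at 65068 and 45089 CPM after PBS and 89983 and 91511 CPM after IL-5, and Cd8b1 at 1174 and 1263 CPM after PBS and 737 and 835 CPM after IL-5.

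Whether microglia and T cells responded differently was tested with the difference of the responses, T cells minus microglia. Lysosomal genes stood higher in that difference, with a median of 0.98 (30 of 36 above 0, camera adjusted p = 5.4e-06; adjusted p = 0.85 with an estimated correlation). Ribosomal protein genes stood lower, with -0.59 (68 of 78 below 0, camera adjusted p = 5.29e-09; adjusted p = 0.804 with an estimated correlation). Oxidative phosphorylation genes, which rose in both cell types, were also lower in the difference, with -0.50 (44 of 58 below 0, camera adjusted p = 0.0122; adjusted p = 0.905 with an estimated correlation). In each of these lists edgeR called 0 members over all genes and 0 adjusted over the list alone. Without microglia IL-5 replicate 1 the medians were 0.54 and -0.32 for lysosomal and ribosomal genes, both past the threshold, and 0.039 for oxidative phosphorylation genes. The last call was also lost without microglia PBS replicate 2 (camera adjusted p = 0.218, median -0.38), T cells PBS replicate 1 (0.246, -0.41), T cells IL-5 replicate 1 (0.0751, -0.40) or T cells IL-5 replicate 2 (0.162, -0.64), and its median was -1.14 without microglia IL-5 replicate 2. After the length adjustment the oxidative phosphorylation median was -0.17 and did not pass (camera adjusted p = 0.52). The ribosomal median was then -0.26 and passed (0.000419).

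No single gene passed the test of the difference in edgeR: 0 of 15397, with 496 higher and 302 lower at an unadjusted p under 0.05 (770 by chance), while DESeq2 called 132 higher and 55 lower. The smallest adjusted p was 0.0648, for Hpgd, which inactivates prostaglandins (8.19, SE 0.90), Prg2 (9.36, SE 1.102) and Sh2d1a, an adaptor of lymphocyte receptors (-11.28, SE 1.23). Across the 12677 genes tested in both cell types, which are not independent replicates, the fold changes had a Pearson r of 0.014 and a Spearman rho of 0.041. The count of genes was 3 without microglia PBS replicate 1, 1 without microglia IL-5 replicate 1, 232 without microglia IL-5 replicate 2, 16 without T cells PBS replicate 1, 18 without T cells PBS replicate 2 and 6 without T cells IL-5 replicate 1.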

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

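The tests of explanations in this part were chosen after the pattern to be explained was seen. Only for the other plasma cell genes was the prediction written before the outcome of its test. The tests of the difference of responses had been planned.

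A test of the difference of the responses to IL-5, T cells minus microglia, called 7 gene lists at the preset correlation. With an estimated correlation none of the 7 passed (adjusted p from 0.804 to 0.905). The medians of the difference were 0.98 for lysosomal genes, -0.588 for ribosomal protein genes and -0.498 for oxidative phosphorylation genes. The last turned to 0.039 without microglia IL-5 replicate 1. TNF and NF-kB genes had -0.414 (31 of 39 below 0, camera adjusted p = 0.0319), and cytotoxicity genes -0.844 (21 of 28 below 0, 0.0319). Markers of NK and innate lymphoid cells had -1.81 (9 of 12 below 0, 0.0205). Markers of eosinophils and basophils had 2.608 (8 of 11 above 0, 0.0319). Of these 11 genes, 7 were at 0 in a group, and with such genes set to 3 counts per library the median was 2.00. Set likewise, the medians were 0.79 for lysosomal genes (1 at 0), -0.37 for TNF and NF-kB genes (7), -0.83 for cytotoxicity genes (2) and -1.98 for NK markers (3). Over genes of at least 20 CPM on average, microglia medians relative to PBS were 0.884 and -0.134 in IL-5 replicates 1 and 2 for cytotoxicity genes. For TNF and NF-kB genes they were 0.345 and -0.023. NK markers summed to 24227 CPM in microglia IL-5 replicate 1 and 7956 to 8978 CPM in the other microglia libraries. The cytotoxicity and NK lists also hold genes of the microglia lists, such as Cx3cr1 and Tyrobp.

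Each of these last 4 calls was lost in several cases where a single library was left out, at medians smaller, similar or larger. The TNF and NF-kB call was lost with library-size scaling (0.0529, median -0.27), with the length adjustment (0.0531, -0.42) and without microglia PBS replicate 1 (0.322, -0.31) or IL-5 replicate 1 (0.307, -0.27). It was also lost without T cells PBS replicate 1 (0.0557, -0.64), PBS replicate 2 (0.0886, -0.42), IL-5 replicate 1 (0.0751, -0.31) or IL-5 replicate 2 (0.162, -0.59). Its median was -0.69 without microglia IL-5 replicate 2. The cytotoxicity call was lost with the length adjustment (0.094, median -0.72) and without microglia IL-5 replicate 2 (0.239, -0.61). It was also lost without T cells PBS replicate 2 (0.383, -0.63), IL-5 replicate 1 (0.0838, -0.55) or IL-5 replicate 2 (0.20, -0.85). Its median was -0.51 without microglia PBS replicate 2. The NK call was lost without microglia PBS replicate 1 (0.0846, median -1.50) or IL-5 replicate 2 (0.112, -1.79). It was also lost without T cells PBS replicate 1 (0.0617, -2.47), PBS replicate 2 (0.0886, -1.84) or IL-5 replicate 2 (0.225, -0.48).

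The eosinophil call was lost with a filter at 5 CPM (0.334, median 1.21) and with library-size scaling (0.0529, 2.44). It was also lost without microglia PBS replicate 2 (0.266, 2.44), IL-5 replicate 1 (0.307, 1.65) or IL-5 replicate 2 (0.0842, 5.04). The same held without T cells PBS replicate 1 (0.191, 2.58), IL-5 replicate 1 (0.0751, 3.23) or IL-5 replicate 2 (0.19, 2.58). Its median was 4.15 without microglia PBS replicate 1 and 4.29 without T cells PBS replicate 2.

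Reads outside annotated genes, which no comparison used, made up 25.494% of microglia IL-5 replicate 1, above the 15.2% and 16.2% of the PBS microglia.

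In the IL-5 microglia libraries, oxidative phosphorylation and ribosomal protein genes were higher and lysosomal genes lower, and IL-5 replicate 1 stood apart, with GC content and transcript length explaining 2.12% and 7.72% of the variance of its log2 ratio to the other microglia libraries. Replicate 1 was not alone in these directions, since without it the medians of the 3 lists moved from 0.967, 0.437 and -0.792 to 0.368, 0.221 and -0.30. That leaves 1 IL-5 library, which cannot tell an effect of treatment from variation between libraries. The data argue against transcript length as the whole source for lysosomal genes (-0.616 after the length adjustment). Transcript length may account for the ribosomal rise, whose call ended because the median fell from 0.437 (SD 0.562 over genes) to 0.042 (SD 0.605), and for part of the oxidative phosphorylation rise, which was 0.435 after the adjustment and still passed (trends fitted without the genes of these lists gave 0.046 and 0.446). Dilution by other RNA alone would lower lysosomal genes and microglia markers alike. Lysosomal genes lay -1.066 from those markers in replicate 1 (permutation p = 0.00517) and -0.042 in replicate 2 (permutation p = 0.676). The permutations treat genes of 1 library as independent, which they are not, so dilution stays open in both replicates. Fewer captured molecules may contribute to the distance of replicate 1, in which 73 genes at 10 CPM or more in the other 3 microglia libraries had under 3 counts, against at most 3 in any other microglia library, and an effect of IL-5 stays open and untested beside these.

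In the IL-5 T cell libraries, choroid plexus genes were higher and T cell and interferon genes lower. The data argue against GC content as the whole source for oxidative phosphorylation genes, whose median of 0.378 was 0.385 after a GC adjustment that moved 8.89% of genes by over 0.1, and against transcript length as their whole source, with 0.29 after the length adjustment, both past the threshold. Choroid plexus RNA that passed the sort by surface markers is a candidate source of the first change. The median over 24 genes other than Ttr, 5 of them in the fixed choroid list, was 0.78, and the other 19 had one of 0.67. The bootstrap interval over the 24 genes, which are not independent, was 0.566 to 0.893. Enpp2 and Kcnj13, the most abundant, measured 16747 and 12007 CPM and 1182 and 855 CPM after PBS. After IL-5 they measured 19842 and 20878 CPM and 1634 and 1741 CPM. Dilution of T cell RNA cannot be told apart from a change within T cells, as 6 naive and memory genes lay 0.392 from the T cell markers (permutation p = 0.0618) and 55 interferon genes -0.158 (permutation p = 0.216), while scaled to those markers the type I interferon (-0.277, camera adjusted p = 0.000132), interferon gamma (-0.164, 0.0286) and exhaustion (-0.186, 0.0377) lists still passed, in a test against all other genes and not against the markers. Whether choroid plexus RNA also raised the oxidative phosphorylation and lysosomal medians was not tested. Oxidative phosphorylation genes summed to 16008 and 13790 CPM after PBS and 17854 and 21086 CPM after IL-5, the same order of libraries as for Ttr. An effect of IL-5 on the T cells stays open and untested beside these.

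Jchain and Prg2 measured at most 7.23 CPM and 0.12 CPM in the PBS T cell libraries and at least 136 CPM and 24.7 CPM in the IL-5 ones. The data argue against RNA from the microglia libraries, since microglia markers reached at most 0.313% of their level in microglia, and Prg2 would need at least 21.5%. Plasma cell RNA that passed the sort by surface markers, which should remove plasma cells and eosinophils, may contribute and stays open. Of 15 other plasma cell genes 3, or 20% against 16.7% by chance, were higher in both IL-5 libraries (exact binomial p = 0.468). Fkbp11 was 1 of these 3, at 25.25 and 12.12 CPM after IL-5. Mzb1 and Derl3 were at 0 CPM in IL-5 replicate 1, the T cell library with the most Jchain. Both were higher in PBS replicate 1 than in IL-5 replicate 2 (13.06 and 8.47 CPM). Their absence from IL-5 replicate 1 cannot decide the question. In that library 93 genes at 10 CPM or more in the other 3 T cell libraries had under 3 counts. Eosinophil RNA stays open too, since 8 other eosinophil genes summed to 0 CPM in IL-5 replicate 1, to 14.2 CPM in IL-5 replicate 2 and to 9.75 CPM in PBS replicate 2, where Prg2 was at 0.12 CPM. Most of these sums came from single genes, Epx (11.8 CPM) in IL-5 replicate 2 and Ccr3 (9.64 CPM) in PBS replicate 2. An effect of IL-5 stays open and untested beside these.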

How the results depend on the processing

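The GC and length adjustments, the scaling to marker lists and the list tests under other filters or with a library left out were chosen after the results were seen, and the other alternatives had been planned. DESeq2 called 18 genes higher and 49 lower in microglia, 403 and 255 in T cells, 187 for the difference of responses, and 1226 and 1623 for T cells against microglia. Without a filter, and with all 8 libraries in one fit, 2 genes were higher in T cells. Without a filter 31 genes differed in response, and 641 were higher and 1081 lower in T cells than in microglia. Library-size scaling gave 919 and 376 there, with the median of all genes at 0.753, and left 1 list higher in the difference of responses. It placed the median of all genes at -0.153 in microglia and 0.149 in the difference. With an estimated correlation 0 lists were called higher and 0 lower in microglia, T cells and the difference. By fry no list passed in microglia (smallest fry adjusted p = 0.159), T cells (0.259) or the difference (0.458). RLE size factors left 1 list lower in microglia, and scaling to the T cell markers left 3 lower in T cells and turned the ribosomal median there to 0.207. With the length adjustment 3 lists were lower in the difference, 2 of the 5 reported and the immediate early and dissociation genes. The cause was not tested.

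With the replicate number as a block, edgeR called 0 genes in microglia, T cells and the difference, with 623, 458 and 563 at an unadjusted p under 0.05, and 167 higher and 400 lower in T cells than in microglia. The MHC class I list in T cells lost its call (camera adjusted p = 0.0616). Libraries with the same number share only a number, and their deviations correlated at 0.014 in microglia and 0.016 in T cells.

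Leaving out 1 library leaves a group of 1, assumed to vary like the other groups. Genes called then ranged from 0 to 532 higher and 0 to 723 lower in microglia, 0 to 1 higher in T cells and 0 to 232 in the difference, and from 134 to 831 higher and 349 to 1197 lower in T cells against microglia. Lists ranged from 1 to 4 lower in microglia, 1 to 5 higher and 4 to 11 lower in T cells, and 1 to 3 higher and 1 to 6 lower in the difference. Values that turned ranged from -0.99 to 1.45 for Csf2rb and -0.91 to 0.40 for Socs2 in microglia, -0.25 to 0.088 for Ifng and -0.12 to 1.09 for Cd4 in T cells, and -1.14 to 0.039 for oxidative phosphorylation genes in the difference. Under the alternatives that kept every library no named gene turned: 1106 values stayed on their side of the threshold, 83 came past it and 14 fell short of it. The alternative pseudocount was not run, as the values are counts. Depth limits a level at 0 counts to 0.0986 CPM in the deepest library and 0.128 CPM in the shallowest.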

Other observations

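The tests of choroid plexus genes in this part were chosen after the result was seen. The following lists did not pass. In microglia, the STAT5 target and IL-5 receptor list had a median log2 fold change of -0.27 (14 of 21 below 0, camera adjusted p = 0.201), and the type I interferon list one of -0.33 (0.486), or -0.17 with 1 member at 0 in a group set to 3 counts per library. The TNF and NF-kB list had a median of 0.10 with a mean of -0.063 (0.694), and the MHC class II list a median of -0.063 with a mean of 0.10 (0.891). The cell cycle list in microglia had a median of -1.28 (21 of 30 below 0, 0.0786), or -0.82 with the 4 members at 0 in a group set to 3 counts per library, and it passed with the GC adjustment, when scaled to the microglia markers and without microglia PBS replicate 1. In T cells, the STAT5 list had a median of -0.28 and a mean of 0.24 (0.631), the regulatory T cell list a median of -0.71 (12 of 16 below 0, 0.0761), and the naive and memory list one of 0.12 (0.828). None of these lists had a member called by edgeR, over all genes or adjusted over the list alone.

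The microglia libraries also carried choroid plexus genes. Over 19 abundant ones other than Ttr the median log2 difference after IL-5 was 0.68 (bootstrap interval over genes 0.249 to 0.888). On TMM-scaled log2 CPM 12 were higher in both IL-5 than in both PBS libraries. On unscaled CPM fewer were, with Igf2 for example at 215 CPM in IL-5 replicate 1 and 231 CPM in PBS replicate 2. The mean Spearman correlation of microglia IL-5 replicate 1 with the other microglia libraries was 0.875, against 0.90 to 0.903 for those. In T cells, genes at 10 CPM or more in the other 3 libraries and under 3 counts in the one in question numbered 93 in IL-5 replicate 1, 53 in PBS replicate 1, 16 in PBS replicate 2 and 3 in IL-5 replicate 2. A gene can therefore be missed in a library, and the folds given against a group at 0 allow for counting error only.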
